A study of Homo sapiens with 4 samples.

How the data were processed

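Gene expression was measured on Affymetrix microarrays in MDA-MB-231Br cells, a derivative of the MDA-MB-231 breast cancer line. The labels' cell line field and growth protocol name MDA-MB-231Br, while the sample titles name MDA-MB-231. Per the labels' protocols, cells were transduced with lentivirus carrying a control short hairpin RNA (shControl) or a short hairpin RNA against YTHDF3 (shYTHDF3) and selected with puromycin. YTHDF3 is a cytoplasmic protein that binds N6-methyladenosine (m6A) on RNA. Total RNA was extracted with Trizol and biotin-labelled cRNA was hybridised, per the labels' protocols. There were 4 arrays, 2 per group, and each sample's group and number were taken from its title. Nothing in the labels says whether the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

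The deposited table held log2 expression values, 1 column per array and 1 row per probe set. RMA is named in the submitters' processing notes. Its version, its settings and the probe annotation used by the authors are not given in the sources used here. RMA corrects background, normalizes between arrays and summarises probes, so array-wide shifts in RNA amount are removed before deposit and weak signals are compressed towards a floor. The values ran from 1.08 to 14.0 and the 4 medians from 3.20 to 3.22, as a log2 scale after normalization between arrays would give. No detection calls were used, and the number of arrays limits the precision.

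Of 53617 probe sets, 16098 had 1 gene symbol in the platform annotation used here, 0 had several and 37519 (70.0%) were unnamed here. All 16098 Entrez identifiers were matched to RefSeq, which changed 0 symbols. Control probe sets could not be told apart among the unnamed ones, so the filter was taken over all rows. The named probe sets covered 14884 genes. Probe sets named YTHDF3, YTHDF1 or YTHDF2 numbered 0. The level of the targeted gene was therefore not analysed here, and the knockdown labels have no check from it. Sialyltransferases and connexins, including ST6GALNAC5 and GJA1, were likewise not analysed here. No coordinates are given, because the array's genome build is not given in the sources used here.

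Each gene was represented by its probe set with the highest mean over the 4 arrays. Genes were tested when that mean reached the 30th percentile of all probe sets (2.54 on the log2 scale), which left 12755 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariates), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The fit had 2 residual and 5.30 prior degrees of freedom per gene, and the median standard error (SE) of a log2 fold change was 0.142. A permutation of 2 arrays against 2 cannot give a 2-sided p below 0.333, so the adjusted p-values rest on the spread that limma shares across genes. A test used simulated data, with the mean levels of these 12755 genes and spreads drawn from limma's fitted prior. There limma recovered 82% of 100 genes changed by 1 on the log2 scale and 98% of 100 changed by 2, with 11 false calls among 191. The simulated noise was independent between genes and followed limma's own model, so these rates need not hold for the real arrays.

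There were 28 gene lists, of which 26 had at least 3 tested members. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Each was adjusted over the lists. With an estimated correlation camera rests on the 2 residual degrees of freedom, which alone makes its p-values larger. Camera compares a list with the other genes. Fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes. Families of genes sharing a symbol prefix were tested in the same way. The lists, tests and alternatives were fixed before the data were examined, apart from those named in the closing section as added.

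The genes named in the text followed a rule: YTHDF3, YTHDF1 and YTHDF2; the 12 largest rises and 12 largest falls past the threshold whose arrays did not overlap between groups, passing over LOC symbols; EGFR, VEGFA, GJA1 and ST6GALNAC5 where tested; and up to 4 members of smallest p from each list described. Only 10 genes with usable symbols passed as rises. Others are named as chosen after their values were seen.

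Nothing in the labels ties the replicate numbers to a shared day or batch, so the comparison was not blocked. Alternatives covered the filter, the probe set rule, 3 further normalizations, the variance model, a replicate block, the threshold, the set test and leaving out each array. The planned restriction by probe set suffix was not run, because probe sets here carry numeric identifiers.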

Results

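Expression was profiled on 4 arrays of MDA-MB-231Br cells (MDA-MB-231 in the sample titles), 2 with the control hairpin and 2 with the hairpin against YTHDF3. The comparison asks which transcripts differ when the m6A reader YTHDF3 is targeted. Values are log2 expression as deposited, given as mean ± SD with n = 2 per group. Across the 12755 tested genes the arrays of a group correlated at 0.992 for both groups, and arrays of different groups at 0.986 to 0.987. The SD of the log2 differences was 0.253 between the control arrays and 0.261 between the knockdown arrays, against 0.323 to 0.342 between groups. The first principal component held 54.6% of the variance and separated the groups.

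Most of the transcripts past the threshold were lower in the knockdown cells. HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, fell from 8.53 ± 0.03 to 5.22 ± 0.25, a log2 change of -3.30 (SE 0.15) or 9.88-fold. DDIT3, the endoplasmic reticulum (ER) stress transcription factor CHOP, fell 8.39-fold. The chaperone gene SDF2L1 fell 7.29-fold and SESN2, a stress-induced inhibitor of mTORC1, fell 5.88-fold. The inducible heat shock genes HSPA1A and HSPA1B fell 6.72-fold and 5.29-fold from high control levels of 11.7 ± 0.17 and 11.9 ± 0.06. These genes are near-identical copies, so their probe sets cannot be taken as separate measurements. DDIT4, another inhibitor of mTORC1, fell 4.41-fold, and the immediate early gene EGR1 fell 4.77-fold. The remaining genes among the 12 largest falls were KRTAP4-8 (7.75-fold), TMEM50B (6.77-fold), MIR222 (4.52-fold) and ATF7IP2 (3.65-fold). The knockdown levels of DDIT3, KRTAP4-8 and ATF7IP2, at 3.49 ± 0.30, 3.36 ± 0.02 and 3.81 ± 0.09, lay near the array medians, where weak signals are compressed, so their folds are not exact and can be understated. Adjusted p-values of the 12 falls, from limma, ran from 0.0004 to 0.0065. A second probe set of TMEM50B moved by only -0.02 on the log2 scale, and a second one of EGR1 by -0.54.

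Rises were fewer and smaller. ENG, the TGF-beta co-receptor endoglin, rose from 7.22 ± 0.11 to 8.27 ± 0.03, which is 2.07-fold. TGOLN2, a trans-Golgi network membrane protein, rose 2.33-fold and NOG, the BMP antagonist noggin, rose 1.93-fold. FITM2, which takes part in lipid droplet formation, rose 2.31-fold. The other named rises were ANKRD36BP1 (2.51-fold), SYNJ2BP (2.34-fold), TMEM19 (2.31-fold), VTRNA1-3 (2.21-fold), BRI3BP (1.91-fold) and RDH11 (1.82-fold). Adjusted p-values of these 10 rises, from limma, ran from 0.010 to 0.046. ANKRD36BP1 and SYNJ2BP had control levels of 2.64 ± 0.19 and 2.91 ± 0.15, close to the filter value of 2.54. Their folds are therefore not exact and can be understated.

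In all, limma called 96 of 12755 genes at an adjusted p under 0.05, 85 lower and 11 higher in the knockdown arrays. Of these, 56 lower and 8 higher genes differed by at least 2-fold. The groups did not overlap for any of the 96, and for 45.5% of all tested genes, where chance gives 33.3% for 2 arrays against 2. USP17L12 and USP17L9P, named after their values were seen, had identical values, so the 96 are at most 95 distinct measurements. The near-identical HSPA1A and HSPA1B are counted apart in these. At an unadjusted p under 0.05, 1082 genes were lower and 796 higher. With limma the count was 0 without shControl replicate 1 and 0 without shControl replicate 2, with 1375 and 1389 genes at an unadjusted p under 0.05. It was 36 without shYTHDF3 replicate 1 and 36 without shYTHDF3 replicate 2. With either control left out the spread rests on the knockdown pair alone, and the lone control array is assumed to vary like them. With an intensity trend in the variance model the count was 375, of which 272 were lower.

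**Figure D1:**
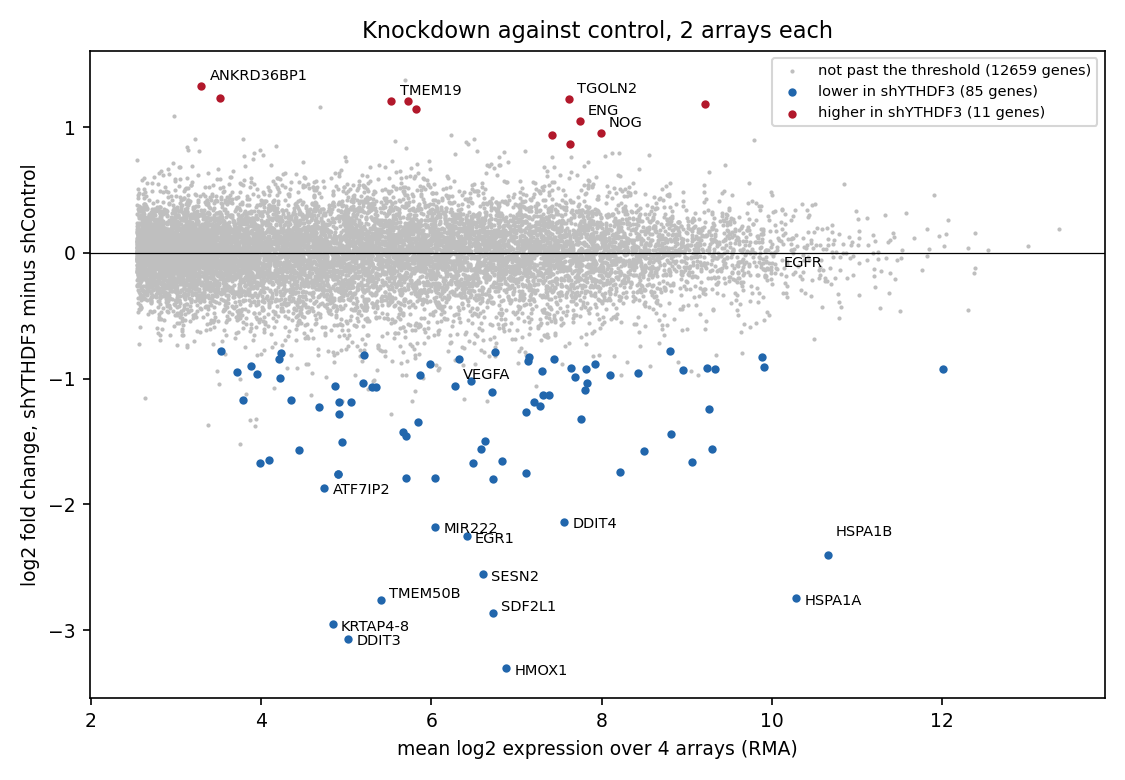
Each point is 1 of the 12755 tested genes, with its mean log2 expression over the 4 arrays on the x axis and its log2 fold change, shYTHDF3 minus shControl, on the y axis. Blue points are the 85 genes past the threshold that were lower and red points the 11 that were higher, with HMOX1 lowest at -3.30.

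The list of unfolded protein response and ATF4 genes, which cells use to meet ER stress and amino acid shortage, had the most members lower of the fixed lists. Camera gave an adjusted p of 7.8e-19 at the preset correlation, against an adjusted p of 0.49 with an estimated correlation. Fry gave an adjusted p of 0.024. The adjustment gave the same 0.49 to lists of unlike unadjusted p. With an estimated correlation camera's unadjusted p was 0.024 for this list. It was 0.20 for the G1/S and DNA replication list and 0.22 for mesenchymal and matrix genes. Of the 15 tested members of the unfolded protein response and ATF4 list 7 fell, 0 rose and 8 did not pass. Adjusted over the list alone, 14 were lower and 0 higher. Besides SDF2L1, SESN2, DDIT3 and DDIT4, the falls were TRIB3, a pseudokinase induced with CHOP (3.37-fold), ASNS, asparagine synthetase (2.50-fold), and XBP1, a transcription factor of the ER stress response (1.99-fold). These last 3 and ATF4 are named after their values were seen. The transcript of ATF4 itself, whose protein is regulated largely at translation, differed by 0.01 on the log2 scale (95% interval -0.29 to 0.31). The list's median log2 fold change was -0.99, and in the 4 pairs of a knockdown with a control array its median ran from -0.86 to -1.10. Single members passed only with both control arrays in the fit. With 1 array left out the list's median ran from -1.11 to -0.88.

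**Figure D2:**
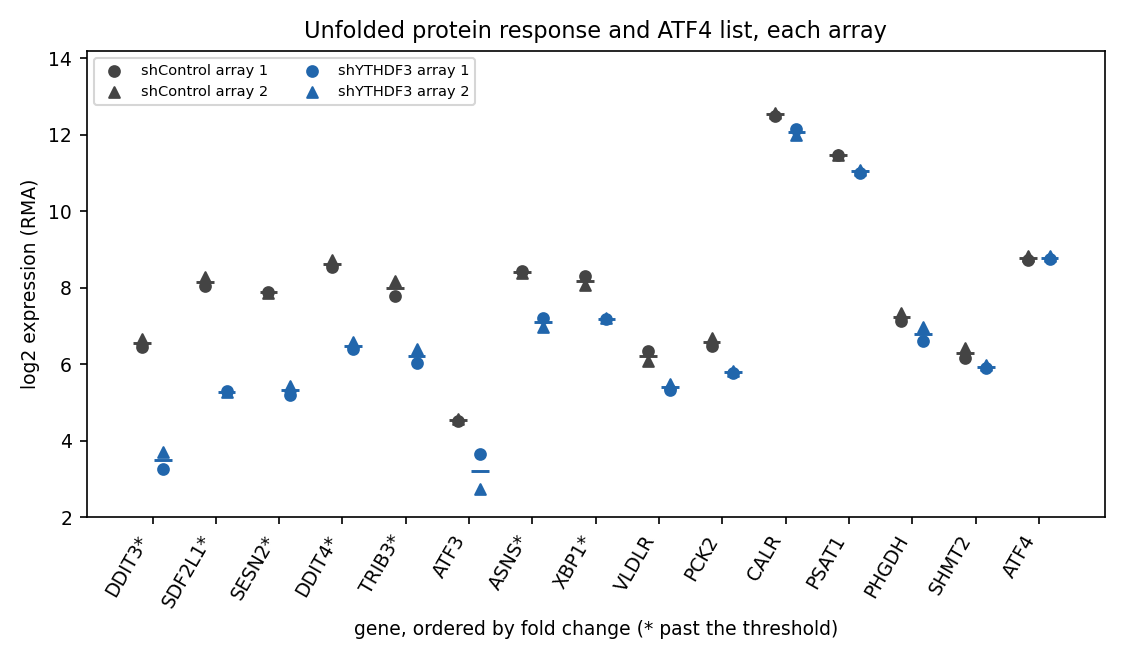
Log2 expression (y axis) of the 15 tested genes of the unfolded protein response and ATF4 list (x axis) on each array, with circles for array 1, triangles for array 2 and bars for group means. The 7 genes with an asterisk passed the threshold, and ATF4 at the right differed by 0.01.

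Genes linked to brain metastasis of breast cancer were lower as a list with camera at the preset correlation (median -0.22, adjusted p = 0.013). The call was lost with the other set tests, at an adjusted p of 0.49 with an estimated correlation and an adjusted p of 0.094 with fry. This list includes genes that earlier work reported for YTHDF3. It may have been chosen partly on cells like these, so its direction is not independent evidence. The arrays measured transcripts only, so an effect on translation or protein was not tested for these genes, EGFR among them. Of 12 tested members 2 fell, 0 rose and 10 did not pass, and adjusted over the list alone 4 were lower. PTGS2, the prostaglandin-forming enzyme COX-2, fell from 9.89 ± 0.17 to 8.64 ± 0.03 (2.37-fold, adjusted p = 0.013 from limma). VEGFA, the main growth factor for blood vessels, fell from 6.80 ± 0.06 to 5.75 ± 0.02 (2.08-fold, adjusted p = 0.018 from limma). LTBP1 and PELI1 had log2 fold changes of -0.68 and -0.65 and did not pass. EGFR, the epidermal growth factor receptor, stood at 10.1 ± 0.03 in control and 9.95 ± 0.09 in knockdown arrays, a log2 difference of -0.16 (95% interval -0.47 to 0.14) with an adjusted p of 0.61 from limma. Without shYTHDF3 replicate 2 the median was -0.13 and camera's adjusted p 0.081, in a range over all alternatives of 0.0075 to 0.49.

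The hypoxia list was lower with a median of -0.18, although VEGFA was the only 1 of its 13 tested members past the threshold. Camera gave an adjusted p of 0.013 and fry 0.024, and the adjusted p was 0.49 with an estimated correlation. Adjusted over the list alone 4 were lower. ANKRD37, LOX and NDRG1 had log2 fold changes of -0.81, -0.74 and -0.46 and did not pass over all genes. Without shYTHDF3 replicate 2 the median was -0.13 and camera's adjusted p 0.065, in a range over all alternatives of 0.011 to 0.49. Mesenchymal and matrix genes had a median of -0.22 over 19 members, of which only FN1, fibronectin, fell (2.83-fold, adjusted p = 0.012 from limma); adjusted over the list alone 2 were lower. LOX, ZEB1 and FBN1 did not pass over all genes, at -0.74, -0.47 and 0.36. Camera's adjusted p was 0.030, the adjusted p was 0.49 with an estimated correlation, and fry's was 0.15. Camera's adjusted p was 0.18 without shControl replicate 2 (median -0.13) and 0.14 without shYTHDF3 replicate 1 (median -0.16), in a range over all alternatives of 0.016 to 0.49.

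Cell cycle genes were higher as lists with camera at the preset correlation, without any single member passing over all genes. Both calls were lost with the other set tests: for G1/S the adjusted p was 0.49 with an estimated correlation, which was itself 0.56, and 0.17 with fry, and for G2/M the adjusted p was 0.51 with an estimated correlation and 0.22 with fry. Of 23 tested genes of the G1/S transition and DNA replication, 22 had a positive fold change, and 8 were higher when adjusted over the list alone. CCNE1, cyclin E1, stood at 5.76 ± 0.16 in control and 6.70 ± 0.23 in knockdown arrays, a log2 difference of 0.93 with an adjusted p of 0.060 from limma. FEN1, MCM10 and GINS2, which act at the replication fork, had differences of 0.76, 0.77 and 0.70. The list's median was 0.34 and camera's adjusted p at the preset correlation 1e-08. Of 23 tested G2 and mitosis genes 22 were also positive, with a median of 0.15, and none passed limma's test adjusted over the list alone, with 6 at an unadjusted p under 0.05. KIF11, KIF20A, MKI67 and CCNA2 had log2 differences of 0.46, 0.46, 0.39 and 0.35. Camera's adjusted p at the preset correlation was 0.0039. Without shControl replicate 2 the median was 0.090 and camera's adjusted p 0.18, in a range over all alternatives of 0.00013 to 0.51.

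**Figure D3:**
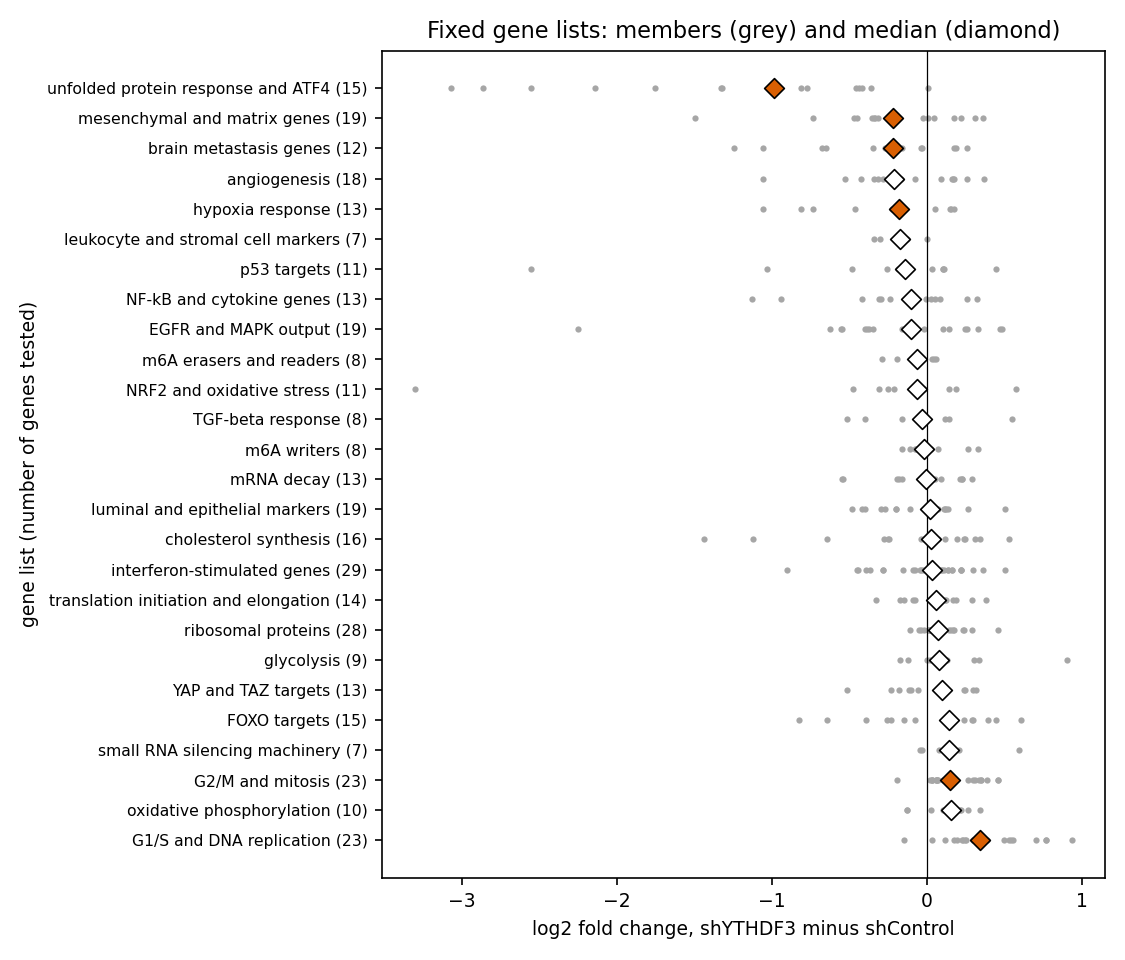
Log2 fold changes (x axis) of the tested members of the 26 fixed lists (y axis, number tested in parentheses) as grey points, with each list's median as a diamond. Filled diamonds mark the 6 lists with camera adjusted p under 0.05 at the preset correlation, from the unfolded protein response and ATF4 list at -0.99 to the G1/S list at 0.34.

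The tested part of the m6A machinery did not differ detectably. Not tested were the writer cofactor CBLL1, the demethylase ALKBH5, the readers YTHDF1, YTHDF2, YTHDC2 and ELAVL1, and YTHDF3 itself. Of 8 tested m6A writers and 8 erasers and other readers none passed with limma, 0 had an unadjusted p under 0.05, and the medians were -0.02 and -0.07 with camera adjusted p-values of 0.79 and 0.62. WTAP and RBM15, of the methyltransferase complex, had log2 differences of 0.33 and 0.26, and the demethylase FTO had -0.20. Interferon-stimulated genes also had no member past the threshold among 29, adjusted over all genes or over the list alone, with a median of 0.03. At an unadjusted p under 0.05 from limma, 2 were higher and 4 lower. IFITM2 and IFIT3 stood at -0.90 and 0.50.

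Single genes passed in lists that did not pass camera's test. Among 13 NF-kB and cytokine genes the chemokines CXCL3 (2.19-fold) and CXCL2 (1.92-fold) fell. Among 11 p53 targets SESN2 and GDF15 (2.04-fold), a stress-induced cytokine, fell. Both also respond to ATF4. STARD4, a sterol carrier, fell 2.71-fold among 16 cholesterol synthesis genes, where INSIG1 stood at 0.53 and HMGCS1 at -0.64 without passing. EGR1 was the 1 of 19 EGFR and MAPK output genes that fell, HMOX1 the 1 of 11 antioxidant genes and VEGFA the 1 of 18 angiogenesis genes. Adjusted over the list alone, the counts lower and higher were 2 and 0 for cytokines, 3 and 0 for p53 targets, 3 and 1 for cholesterol synthesis, 4 and 2 for MAPK output, 1 and 1 for antioxidant genes, and 1 and 0 for angiogenesis. Camera's adjusted p for these lists ran from 0.10 to 0.77.

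No tested member passed limma's test over all genes in the lists of glycolysis (9 of 19 tested) or oxidative phosphorylation (10 of 32). The same held for ribosomal proteins (28 of 47), translation factors (14 of 38), mRNA decay (13 of 27) and TGF-beta response (8 of 20). It also held for YAP and TAZ targets (13 of 23), FOXO targets (15 of 22) and small RNA silencing (7 of 15). Members that were not tested are not covered. At an unadjusted p under 0.05 these lists had between 0 and 3 lower and between 0 and 2 higher members. Their medians ran from -0.03 for TGF-beta response to 0.15 for oxidative phosphorylation. The transcript of FOXO3, reported elsewhere as a YTHDF3 target, had a log2 difference of 0.61 with an adjusted p of 0.17 from limma. Its protein was not measured. Adjusted over the list alone, 1 glycolysis gene (PGAM1, 0.91), 1 silencing gene (DGCR8, 0.59) and, among FOXO targets, 1 higher and 2 lower genes passed. Markers of other cell types were tested for a difference between the groups. Such a test cannot show whether all cultures held other cells alike. None of 19 luminal and epithelial markers passed with limma (median 0.02, 1 lower and 1 higher at an unadjusted p under 0.05). None of 7 leukocyte and stromal markers passed (median -0.17, 1 lower at an unadjusted p under 0.05). Camera's adjusted p for the latter was 0.11, and 0.044 without shControl replicate 1, in a range over all alternatives of 0.044 to 0.49. Of the gap junction list only the pannexins PANX1 and PANX2 were tested, at 0.20 and 0.29, and neither passed. The sign of median, mean and camera's direction differed for m6A writers, interferon-stimulated genes, cholesterol synthesis and luminal markers. For FOXO targets fry's direction opposed camera's, with a mean of 0.0005.

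Among the families defined by symbol prefix, 7 had enough tested members, and none shifted at the preset correlation. The kinesin family (KIF) came closest, with 30 of 42 positive, a median of 0.12 and a camera adjusted p of 0.060. Zinc finger genes (ZNF) had 4 of 457 lower and 0 higher, genes starting with KRT had 2 of 92 lower, and SLC genes 1 of 32. The families SNHG, COL and PCDH had 0 genes past limma's threshold, with 3, 1 and 2 at an unadjusted p under 0.05. Median and mean differed in sign for SNHG, COL and SLC. Of the 96 genes, 9 had a total of 18 further probe sets above the filter. Of these, 8 belong to the near-identical HSPA1A and HSPA1B and are no separate measurements. Of the other 10, 9 had the same sign as the chosen probe set, but most moved far less. TMEM50B moved -0.02 against -2.76, WARS1 -0.13 against -0.97 and HYOU1 -0.16 against -0.91. EGR1 moved -0.54 against -2.25, and LINC00999 -0.74, -0.46 and -0.31 against -0.93. RPL26L1-AS1 went the other way (0.05 against -0.95), and 2 of MIR4454 were identical to the chosen one. All of these but TMEM50B and EGR1 are named after their values were seen.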

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

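The tests of explanations below were chosen after the results were seen. Among unnamed probe sets, which the comparison above did not use, large differences were more frequent between the groups than in other splits, but none passed a test. Of 23816 above the filter, 37 differed by at least 2 on the log2 scale between group means, 25 lower and 12 higher in the knockdown arrays. The other ways of splitting the arrays into pairs gave 25 and 20 such probe sets. Limma on the unnamed probe sets called 0 (smallest adjusted p 0.18), with 2229 at an unadjusted p under 0.05. The largest falls were probe sets 16819325 (-3.58) and 16889725 (-3.35), and the largest rises 16880244 (2.85) and 16908613 (2.67). Some carry close identifiers, such as 16889725, 16889727 and 16889736 among the falls and 16771533 and 16771538 among the rises. Whether these are separate loci is not known, so the counts may overstate the number of distinct differences.

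The fall of the unfolded protein response and ATF4 list was weighed against 3 explanations. A single deviating array would leave at least 1 of the 4 array pairs above -0.5, but the weakest still had a median of -0.86. Scaling between arrays moves genes of one level alike, but the members lay a median of -0.98 from the 200 genes nearest to each in mean level. The control cultures may have been under more stress at harvest: heat shock and immediate early genes, lists added after seeing the data, had medians of -0.34 and -0.31 (for both, adjusted p = 0.056 with an estimated correlation), with 4 of 12 and 2 of 24 members past the threshold, while the list's median differed by only 0.10 between the control arrays. These added lists hold HSPA1A, HSPA1B and EGR1, already seen to fall, so they are no independent sign of stress. Evenly stressed controls and an effect of the hairpin cannot be told apart with 1 hairpin against 1 control.

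For the surplus of lower over higher genes (85 against 11), scaling between arrays was weighed too. Scaling left in the deposited values would move most genes alike. The median of all tested genes was 0.004, while 56 of the 85 lower genes fell at least 2-fold. These values argue against a left-over shift common to all genes. Shifts that depend on level were not compared for the 85 as a set, and RMA removes array-wide shifts before deposit, so both stay open. Lower genes made up at least 87.0% of those called under each of 3 further normalizations, but these moved the median of all genes only to between 0.0009 and 0.015, from 0.004, so they could hardly have changed the share. At an unadjusted p under 0.05 the split was 1082 lower against 796 higher, and with an intensity trend in the variance model 72.5% were lower. A biological effect of the knockdown stays open too, untested.

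The higher G1/S list may owe its size to variation from culture to culture in genes that move together. Within the knockdown pair the list's median differed by 0.56 of the group difference. Its median was positive in all 4 array pairs (0.16 to 0.55). With 2 arrays per group, such variation and a difference in proliferation between the groups cannot be told apart.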

How the results depend on the processing

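The main count of 96 genes (85 lower, 11 higher) depended on the arrays included and on the estimate of spread. It was 375 (272 lower, 103 higher) with an intensity trend and 394 (282 lower, 112 higher) with a trend and robust prior. The filter at the 50th percentile gave 167 (141 lower, 26 higher), with fewer genes tested, and no filter gave 5 higher genes. Testing every named probe set gave 21 higher. An adjusted p under 0.01 left 26, all lower (0 higher), and a 2-fold minimum left 56 lower. Testing named and unnamed probe sets together, an alternative added after seeing the data, gave 19 (18 lower, 1 higher). Counting identical rows once was added too and changed no count by over 1.5 times. With the replicate number as a block the count was 11 (11 lower, 0 higher); the correlation of same-numbered arrays' deviations from their group means was 0.04 across genes, so the numbers are not known to pair the arrays, and the block takes 1 of the 2 residual degrees of freedom. Leaving out 1 array gave 0 to 36 genes (0 to 36 lower, 0 to 2 higher), with 0 when either control was left out. The 3 further normalizations gave 92 to 118, and between 89 and 96 of the main genes were shared with them. All 29 named genes past the threshold kept their sign under every alternative run, and all 29 lost the call without either control array. The 6 list calls with camera were lost with an estimated correlation (adjusted p 0.49 to 0.51), at unchanged medians of -0.99 for the unfolded protein response and ATF4 list, 0.34 for G1/S, 0.15 for G2/M, -0.22 for brain metastasis genes, -0.18 for hypoxia and -0.22 for mesenchymal genes. Fry kept the first and the hypoxia list and lost G1/S (0.34), G2/M (0.15), brain metastasis (-0.22) and mesenchymal genes (-0.22). Camera with an estimated correlation rests on 2 residual degrees of freedom, so its losses alone do not show that members move together. The adjusted p of 0.49 is shared by lists of unlike unadjusted p. Camera's unadjusted p was 0.024 for the unfolded protein response and ATF4 list and 0.22 for mesenchymal genes. For hypoxia the estimated correlation was -0.055, below the preset 0.01, yet camera's unadjusted p rose from 0.0024 to 0.085. The mesenchymal list also lost its call at the 50th percentile filter (-0.22), with the mean of probe sets (-0.19) and with every probe set tested (-0.19); its adjusted p over all alternatives ran from 0.016 to 0.49. With 1 array left out the medians ran from -0.28 to -0.13 for mesenchymal genes, 0.090 to 0.29 for G2/M, -0.26 to -0.13 for brain metastasis genes, -0.20 to -0.13 for hypoxia, -0.25 to -0.058 for leukocyte and stromal markers and -0.23 to -0.14 for p53 targets, the last 2 passing in 1 such setting each. The unfolded protein response and ATF4 list stayed past the threshold under each left-out array (-1.11 to -0.88). Of the 26 lists, 9 changed the sign of their median under some alternative, 0 of them past the threshold. Apart from fewer genes or arrays tested, the cause was not tested. The planned restriction by probe set suffix and the level of YTHDF3 itself were not run. Signal near the floor limits low genes such as ANKRD36BP1.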

Other observations

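All the lists and tests in this part were chosen after results were seen, the synthetase comparison among them. ER folding, degradation and stress genes outside the fixed list were chosen with results in view, so they are no independent support for its fall. Of 19 tested, 9 fell and 0 rose, with a median of -0.91. They included the ER stress sensor kinase EIF2AK3 (PERK), at -1.67, the secreted ER protein MANF, at -1.65, and SEL1L, a part of the ER degradation ligase, at -1.56. Adjusted over the list alone 14 were lower and 1 higher. Camera's adjusted p over the added lists was 1.7e-14 (with an estimated correlation, adjusted p = 0.056 and unadjusted p = 0.013). As the list holds genes already seen to fall, this p is no separate test of that fall. Of 12 heat shock genes 4 fell, namely HSPA1A, HSPA1B, HSPA6 (-1.57) and the cochaperone BAG3 (-1.13), while HSPA4 (0.26), STIP1 (0.25) and HSPD1 (0.14) did not pass; adjusted over the list alone 5 were lower. Of 24 immediate early genes EGR1 and DUSP1 (-1.66) fell, and adjusted over the list alone 6 were lower. Camera's adjusted p was 1.4e-05 for both lists (adjusted p = 0.056 with an estimated correlation). Both lists hold genes already seen to fall, so these p-values are no separate test either. The near-identical HSPA1A and HSPA1B also count as 2 members of the heat shock list. The cystathionine gamma-lyase gene CTH (-1.74), the immune checkpoint ligand CD274 (-1.03) and the hyaluronan synthase HAS2 (-1.57) fell as well.

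Among small RNA loci, some microRNA genes fell. The host or precursor signals of MIR222 (-2.18), MIR100 (-1.79), MIR21 (-1.27), MIR1269A (-0.96), MIR584 (-0.90) and MIR4454 (-0.88) fell. These were 6 of 584 tested MIR loci, and 0 rose. Over all 12755 tested genes 85 fell and 11 rose, so the 6 do not set MIR loci apart. Adjusted over the family alone 21 were lower and 2 higher (median -0.05, camera adjusted p 0.052). All 8 tested snaR loci, near-identical small noncoding RNAs whose signals are not independent, were positive with a median of 0.57, none passing over all genes and 5 passing adjusted over the family alone (adjusted p = 0.073 with an estimated correlation). Whether array signal for such loci reflects mature small RNA was not tested.

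Cytosolic tRNA synthetase genes offer a limited check of the hypothesis that ATF4 output was lower, since ATF4 is known to induce some of them. WARS1, GARS1 and SARS1 had been seen to fall (-0.97, -0.83 and -0.78) before the comparison was chosen, and they are among its members, although a second probe set of WARS1 moved by only -0.13. The 12 synthetases known as ATF4-induced were all negative, with a median of -0.29, and the 5 others tested were all positive, with a median of 0.21 (1-sided exact permutation p over genes = 0.0034; genes are not independent replicates). Leaving out the 3 that passed, the remaining 9 had a median of -0.17 (p = 0.0075, 1-sided exact permutation over genes). Lower ATF4 output foresees a fall of the ATF4-induced genes but no rise of the others. The others' median of 0.21 adds to the difference in both tests, so neither tests the fall alone. The 12 negative values are of the sign that lower ATF4 activity would give, though 9 of the 12 did not pass. The ATF4 transcript itself differed by 0.01 (95% interval -0.29 to 0.31). These values do not say whether the hairpin or the state of the cultures was behind the fall.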
